A study of Homo sapiens with 20 samples.

How the data were processed

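The deposited files hold raw counts of reads per Ensembl gene ID, 57773 IDs in each of 20 libraries. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.13 to GRCh37 and counted with HTSeq before the files were deposited. The HTSeq version, the annotation release and the strand setting are not given in the sources used here. Symbols were found for 51996 IDs (90.0%) in a table of a later reference, which served only for names, gene types, gene order, GC content and length, so no coordinates are given.

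HMLE 1 to 3 and NAMEC8 1 to 3 had 3 technical libraries each, which were summed, while NAMEC8 4 and N8-CTx had 1 library each. This left 8 biological libraries and 5 residual degrees of freedom. The labels name biological replicates without saying how they were grown, so p-values measure the spread between these samples.

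Genes were filtered with filterByExpr, which left 18170, and scaled with TMM factors. Groups were compared in 1 fit with the edgeR quasi-likelihood F test (robust dispersions), and p-values were adjusted by the Benjamini-Hochberg (BH) method with a threshold of 0.05. SE values are the log2 change divided by the root of F. CPM values are TMM-normalised, and log2 CPM used a prior count of 2. The block fit added a term for NAMEC8 4 and N8-CTx against all other libraries, so that there N8-CTx against NAMEC8 rests on N8-CTx minus NAMEC8 4. As N8-CTx has a group term of its own, the block term is estimated from NAMEC8 4 against NAMEC8 1 to 3. In that fit NAMEC8 against HMLE rests on NAMEC8 1 to 3. Where the lower group had no count, a fold is given as a bound with 3 counts over the group. Where it had 1 to 3 counts, a ratio with a 95% interval is given. Both cover counting error only and count the zeros of NAMEC8 3, so some are also given without that library, a choice added after the data were seen.

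The tests, the alternatives, the naming rule and 28 gene lists (692 genes, 680 matched to the files) were fixed before the data were examined. The block for the comparison of NAMEC8 with HMLE, the removal of GC trends, the restriction to protein-coding genes, the use of NAMEC8 1 and 2 alone and the search for runs of neighbouring genes were added after. In each comparison the 10 largest increases and decreases were named among genes with a symbol, adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between libraries of the groups. To these came up to 4 members per list and comparison with the smallest adjusted p in each direction, members going against their list, and a fixed set: CDH1, EPCAM, GRHL2, ESRP1, OVOL2, VIM, CDH2, FN1, ZEB1, ZEB2, SNAI2, TWIST1, PRRX1, CD44, CD24, PRKACA, PHF2, CREM, PDE4D and NR4A1. The text names only a part of the genes picked by this rule, and 2 of those left out are not reported here.

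The lists were epithelial junction and adhesion, epithelial transcription and splicing factors, basal epithelial genes, luminal mammary genes, keratinocyte cornification genes, EMT (epithelial-mesenchymal transition) transcription factors, mesenchymal cytoskeleton and adhesion, fibrillar and interstitial matrix, matrix proteases, TGF-beta and BMP pathway, Wnt pathway, CREB target genes, PKA and cAMP machinery, mammary stem and CD44-high markers, EGF receptor ligands and receptors, receptor tyrosine kinases, interferon response, inflammatory cytokines, cell cycle, glycolysis and hypoxia, sterol synthesis, and unfolded protein and amino acid stress. Marker lists for other cell types were endothelial, leukocyte, smooth muscle and myoepithelial, and adipocyte, and RNA quality lists were mitochondrial transcripts and replication-dependent histones. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists in each comparison, with camera at an estimated correlation and fry as alternatives. Camera compares a list with other genes, while fry, without that comparison, asks whether the members shifted in a common direction. Neither value given here tests for changes of members in both directions. Members were also adjusted over the list alone.

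The move toward HMLE was measured with genes called at least 2-fold apart between HMLE 1 to 3 and NAMEC8 1 to 3, and with N8-CTx minus NAMEC8 4 as the change, so that no library was used on both sides. Runs were sought with windows of 41 neighbouring protein-coding genes of mean log2 CPM of at least 3, against 100 shuffles of gene order.

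The pipeline was tested on simulated data. For NAMEC8 against HMLE, 24.0, 90.0, 100.0 and 98.0% of 50 genes each changed 2, 4, 8 and 16-fold were called, and 7.69% of calls were false. For N8-CTx against NAMEC8 the shares were 4.0, 58.0, 82.0 and 94.0%, and 4.8% of calls were false. For NAMEC8 against HMLE, of 20 lists of 25 genes changed 2-fold, 20 were called, and of 20 unchanged lists none was. The simulated genes were independent of each other, so this does not test camera calls of lists with correlated members. List tests with N8-CTx were not simulated. With no change undone, 50.58% of genes lay toward HMLE with disjoint controls and 55.95% with shared controls, and with all of it undone 95.54% and 98.76%.

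Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, and data.table at version 1.17.8.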

Results

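Gene expression was measured by stranded mRNA sequencing in HMLE cells, in NAMEC8 cells and in N8-CTx cells. HMLE is an established line of immortalised human mammary epithelial cells. NAMEC8 is a mesenchymal counterpart of that line. N8-CTx cells were obtained from NAMEC8 by adding cholera toxin every 2 days for 14 days. Cholera toxin keeps the stimulatory G protein of adenylyl cyclase active and so raises cyclic AMP. The comparison of the first 2 groups asked which genes separate the epithelial from the mesenchymal state, and the comparisons of N8-CTx asked how far expression moved back after the toxin. There were 3 biological libraries of HMLE, 4 of NAMEC8 and 1 of N8-CTx, each grown in the same mammary epithelial medium. HMLE 1 to 3 and NAMEC8 1 to 3 were each sequenced as 3 technical libraries, whose counts differed by about the sampling noise (chi-square per degree of freedom 0.990 to 1.02), so they were summed and counted as 1 sample. Counts assigned to genes came to 30602535, 30144738 and 37272250 in HMLE 1 to 3, to 39653169, 33663089, 40100181 and 46355415 in NAMEC8 1 to 4, and to 44113115 in N8-CTx.

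Pairs of HMLE libraries correlated at 0.987 to 0.989 (Pearson's r of log2 CPM across genes, which are not independent replicates). NAMEC8 1 to 3 correlated with each other at 0.961 to 0.986 and with NAMEC8 4 at 0.931 to 0.959. N8-CTx correlated with HMLE libraries at 0.904 to 0.908, within the range of HMLE with NAMEC8 (0.873 to 0.91). With NAMEC8 1 to 3 it correlated at 0.801 to 0.837 and with NAMEC8 4 at 0.882. Along the first principal component, with 56.7% of the variance, HMLE and N8-CTx lay at −136 to −93.5 and NAMEC8 at 74.4 to 141. The second component, with 24.5%, placed NAMEC8 4 at −96.0 and N8-CTx at −137, while the other 6 libraries lay at 6.23 to 65.1. NAMEC8 4 and N8-CTx were also the libraries without technical replicates, so the number of genes called in each comparison is given also from a fit with these 2 libraries as one block, called the block fit here. As N8-CTx had 1 library, its spread was assumed to be that of the other groups, and none of its differences has a replicate check of its own.

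Most transcripts of epithelial junctions were lower in NAMEC8 cells. CDH1, which encodes E-cadherin (ENSG00000039068), stood at 401 ± 46.0 CPM in HMLE (SD, n = 3) and at 0.748 ± 0.456 CPM in NAMEC8 (SD, n = 4), 532-fold lower. EPCAM, another epithelial adhesion gene, went from 123 ± 4.28 to 1.15 ± 0.636 CPM. The desmosomal and adherens junction gene JUP (304 ± 47.7 against 7.92 ± 1.51 CPM) and the P-cadherin gene CDH3 (508 ± 63.3 against 1.96 ± 0.807 CPM) fell as well. Of 34 tested genes of the list of epithelial junction and adhesion, 31 fell and none rose (32 and 0 adjusted over the list alone), with a median log2 change of −4.42. The list moved down against other genes (camera, BH-adjusted p = 6.23e-22, and adjusted p = 0.0351 with an estimated correlation).

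Basal epithelial genes and genes of keratinocyte cornification fell as well. TP63, the master regulator of basal epithelium, went from 380 ± 38.7 CPM in HMLE to 0.429 ± 0.420 CPM in NAMEC8, and KRT15 and the giant cadherin FAT2 had log2 changes of −6.45 and −8.36. In the basal list 26 of 27 tested genes fell (27 adjusted over the list alone; median −6.67, or −6.45 with genes at 0 set to their bound), and in the cornification list 16 of 21 fell (19 adjusted over the list alone; median −6.32, or −4.33 with genes at 0 set to their bound and −3.89 with bounds that leave out NAMEC8 3). Both lists moved down in camera (BH-adjusted p = 2.07e-22 and 1.46e-14, and adjusted p = 0.0351 and 0.0432 with an estimated correlation). The cornified envelope gene SPRR1B had 1 count in all NAMEC8 libraries against 11.7 ± 2.42 CPM in HMLE, a ratio of 1798 (95% counting interval 322 to 71070), or of 1326 (237 to 52400) without NAMEC8 3, a library with few genes of 1 to 3 counts.

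Factors that maintain epithelial identity went the same way. The splicing regulator ESRP1 (194 ± 19.1 against 0.468 ± 0.103 CPM) and the transcription factor GRHL2 (64.3 ± 17.1 against 0.0954 ± 0.0817 CPM) fell, and OVOL2 had no count in any NAMEC8 library, at least 166-fold lower (123-fold without counting NAMEC8 3) than its 3.25 ± 0.803 CPM in HMLE. Of 19 tested genes of this list 13 fell and 2 rose (15 and 3 adjusted over the list alone; camera adjusted p = 4.18e-08, and adjusted p = 0.0788 with an estimated correlation). The risers were GATA3, a luminal regulator (log2 change 0.84, edgeR BH-adjusted p = 0.0199), and the zinc finger gene KLF4 (1.00, adjusted p = 0.0355). Both calls were lost when any HMLE library was left out (adjusted p 0.0723 to 0.101 for GATA3 and 0.0946 to 0.157 for KLF4), and that of KLF4 also without NAMEC8 2 (0.0547) or NAMEC8 3 (0.0502).

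Mesenchymal genes were higher in NAMEC8. Vimentin (VIM) rose from 748 ± 74.7 CPM in HMLE to 4496 ± 355 CPM in NAMEC8 and fibronectin (FN1) from 7669.9 ± 1469 to 33328 ± 1239 CPM, where it took 3.069 to 3.405% of all counts of a library. CDH2, the N-cadherin gene, rose 18.1-fold. Larger changes were found for matrix genes, with the basement membrane linker NID1 at 0.476 ± 0.0416 and 232 ± 40.6 CPM, the elastic fibre gene FBLN5 at 2.76 ± 0.358 and 431 ± 90.4 CPM, and the proteoglycan DCN at 0.913 ± 0.101 and 790 ± 245 CPM. In the list of fibrillar and interstitial matrix 29 of 36 tested genes rose and 2 fell, both also adjusted over the list alone (median 3.99; camera adjusted p = 3.79e-19, and adjusted p = 0.0351 with an estimated correlation). The 2 that fell were the microfibril gene MFAP5 (−9.09 on the log2 scale) and TGFBI (−2.07). In the list of mesenchymal cytoskeleton and adhesion 17 of 28 rose and 2 fell (19 and 2 adjusted over the list alone; camera adjusted p = 4.42e-08, and adjusted p = 0.0432 with an estimated correlation). COL6A2, another collagen gene, was at 1034 CPM in NAMEC8 4 and at 212.5 to 256.9 CPM in NAMEC8 1 to 3.

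Several transcription factors of the epithelial-mesenchymal transition rose in NAMEC8 and others fell. ZEB1 (1.68 ± 0.319 against 130 ± 19.8 CPM), ZEB2 (0.912 ± 0.186 against 55.4 ± 9.70 CPM), TWIST1 (11.8 ± 0.689 against 107 ± 19.7 CPM) and the homeobox gene PRRX1 (0.945 ± 0.460 against 233 ± 88.3 CPM) were higher. SNAI2, which encodes Slug, was 1.73-fold lower (log2 change −0.79 ± 0.16 SE, adjusted p = 0.00545). Of 19 tested transcription factors of this list 10 rose and 4 fell (11 and 5 adjusted over the list alone). This list moved up in camera (adjusted p = 0.000999), a call that was lost at adjusted p = 0.226 with an estimated correlation. CD44 did not differ (1219.9 ± 137 against 1041 ± 215 CPM, adjusted p = 0.516), and CD24, fixed in advance as a companion marker, was not among the genes tested.

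Other groups shifted in part. Inflammatory cytokines were lower for 14 of 22 tested genes (15 adjusted over the list alone, where 1 rose), led by IL1B at 23.3 ± 3.59 and 0.0353 ± 0.0397 CPM (camera adjusted p = 1.09e-06, lost at adjusted p = 0.271 with an estimated correlation). Smooth muscle and myoepithelial genes, a marker list for another cell type, were higher for 6 of 12 (8 adjusted over the list alone; camera adjusted p = 2.34e-05, lost at adjusted p = 0.0788 with an estimated correlation), among them TAGLN and the endopeptidase gene MME with log2 changes of 3.59 and 4.65. Mitochondrial transcripts, kept as a sign of RNA quality, were higher in NAMEC8 for 4 of 13 (7 adjusted over the list alone, 10 with NAMEC8 1 and 2 alone and 8 in the block fit; camera adjusted p = 0.00178, lost at adjusted p = 0.499 with an estimated correlation and at 0.0522 with fry). Their share of counts was 0.888 to 1.17% in HMLE, 1.24 to 1.43% in NAMEC8 1 to 3, 2.27% in NAMEC8 4 and 2.68% in N8-CTx. The highest shares were thus those of the libraries without technical replicates. Cell cycle genes rose for 10 of 35, also adjusted over the list alone, with E2F1 and TPX2 up by 1.92 and 1.68 (camera adjusted p = 0.00891, lost at adjusted p = 0.226 with an estimated correlation).

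Among genes of at least 10 CPM in the higher group, the largest rises in NAMEC8 by fitted fold included those of ABCA8, BNC2 and GLIS1, which had no count in HMLE and were at least 669-fold, 519-fold and 351-fold higher, and, in no order, of ANGPT1, LRRTM3, PNMA2, COL6A2, CLEC3B, DOK5 and DCN. Among the largest falls by fitted fold were those of the chloride channel gene ANO1, CNTN1, IL1RN, SPRR1B, the connexin gene GJB6, KLK10, TP63, MMP9 and RNF43. Of 18170 tested genes 3895 differed between NAMEC8 and HMLE (edgeR quasi-likelihood F test, BH-adjusted), 1845 higher and 2050 lower, of which 1480 and 1673 changed at least 2-fold. The block fit called 5806 genes, 3872 of them in common and in the same direction. Without HMLE 2 the count was 2573, and with NAMEC8 1 and 2 alone it was 6029.

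**Figure D1:**
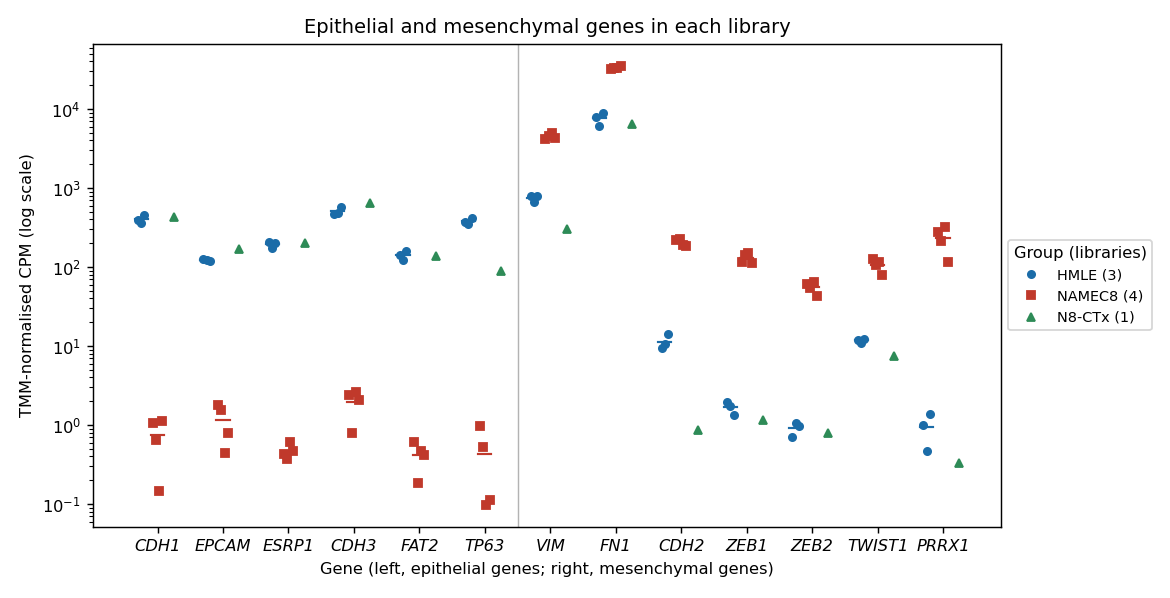
TMM-normalised CPM on a log scale of 6 epithelial genes (left) and 7 mesenchymal genes (right) in every biological library, with a short line at the mean of each group of more than 1 library. N8-CTx, 1 library, lies near the 3 HMLE libraries for most of these genes and apart from the 4 NAMEC8 libraries.

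One group of genes that were higher in NAMEC8 lay side by side. On chromosome 20 a run of 175 consecutive expressed protein-coding genes, from NANP to PCMTD2 in annotation order, had a median log2 difference of 1.18 between NAMEC8 and HMLE. Of its genes 127 were called higher and 3 lower, and they made up 6.88% of all higher calls. The run was 2.31, 2.17, 2.06 and 2.24-fold above other genes in NAMEC8 1 to 4 and 1.73-fold in N8-CTx, both against HMLE. E2F1, TPX2 and DOK5, named above, lie in it, as does MMP9, which went against the run. AURKA and UBE2C, like E2F1 and TPX2 members of the cell cycle list, lie in it too. The rise of that list in NAMEC8 thus overlaps the run. This run was found in the data and was not fixed in advance.

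**Figure D2:**
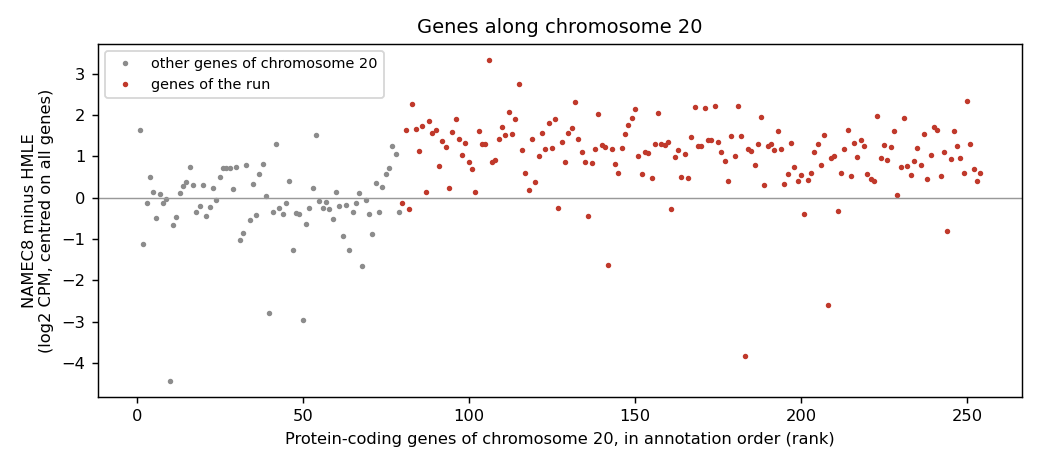
Mean log2 CPM difference between NAMEC8 (4 libraries) and HMLE (3 libraries), centred on all genes, for the expressed protein-coding genes of chromosome 20 in annotation order. The 175 genes of the run, in red, scatter about a median of 1.18, and the other genes of the chromosome, in grey, about 0.

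In N8-CTx, obtained with cholera toxin, most epithelial genes were higher than in NAMEC8. Counts from 1 library of many cells do not show whether the same cells changed. CDH1 was at 426 CPM in N8-CTx, 564-fold above NAMEC8, EPCAM at 167 CPM, ESRP1 at 200 CPM and GRHL2 at 54.7 CPM, and OVOL2 was at least 116-fold higher than in NAMEC8 (85.7-fold without counting NAMEC8 3). Of 34 junction and adhesion genes 31 rose and 1 fell (31 and 2 adjusted over the list alone; median 5.55; camera adjusted p = 6.07e-16, and adjusted p = 0.0365 with an estimated correlation). The one that fell was the plakophilin gene PKP2 (−1.10 on the log2 scale, edgeR adjusted p = 0.00657). Basal genes rose for 24 of 27 and fell for none (24 and 1 adjusted over the list alone), cornification genes for 16 of 21 (18, with 1 lower, adjusted over the list alone, and 11 in the block fit), and epithelial transcription and splicing factors for 15 of 19 with 1 lower, also adjusted over the list alone. Camera called these 3 lists up (adjusted p = 1.8e-13, 6.05e-12 and 1.69e-07), calls that were lost with an estimated correlation (adjusted p = 0.0555, 0.0555 and 0.091). The median of the cornification list was 7.67, or 5.33 with genes at 0 set to their bound and 4.89 with bounds that leave out NAMEC8 3.

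Mesenchymal genes fell in N8-CTx. VIM was at 306 CPM, 14.7-fold below NAMEC8, FN1 at 6554 CPM and CDH2 at 0.856 CPM, 239-fold below NAMEC8. ZEB1 (1.17 CPM), ZEB2 (0.794 CPM), TWIST1 (7.37 CPM) and PRRX1 (0.334 CPM) had log2 changes of −6.79, −6.12, −3.85 and −9.43, while SNAI2 (71.1 CPM) did not pass the test (log2 change −0.34, adjusted p = 0.322). Fibrillar and interstitial matrix genes were lower for 31 of 36 and higher for 2 (32 and 2 adjusted over the list alone; median −3.87; camera adjusted p = 6.96e-17, and adjusted p = 0.0365 with an estimated correlation). The 2 higher ones, MFAP5 and TGFBI, were those that had been lower in NAMEC8. In the mesenchymal list 16 of 28 fell and 2 rose (17 and 2 adjusted over the list alone), and among the transition's transcription factors 11 of 19 fell and 2 rose (13 and 2 adjusted over the list alone). The camera calls of these lists (adjusted p = 6.64e-07 and 1.49e-06) were lost with an estimated correlation (adjusted p = 0.0555 and 0.091). Inflammatory cytokines rose for 14 of 22 and fell for 1, also adjusted over the list alone (camera adjusted p = 0.000342, lost at adjusted p = 0.446 with an estimated correlation), with IL1B at 12.5 CPM and IL1A at 266 CPM.

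Cell cycle genes fell in N8-CTx, both against NAMEC8 and against HMLE. RRM2, a subunit of ribonucleotide reductase, was at 17.0 CPM in N8-CTx, 476 ± 41.6 CPM in NAMEC8 and 280 ± 18.8 CPM in HMLE, and the mitotic kinesin KIF20A was at 7.85, 186 ± 14.3 and 139 ± 7.75 CPM. Against NAMEC8 33 of 35 tested genes fell, also adjusted over the list alone (median −3.76; camera adjusted p = 2.5e-23, and adjusted p = 0.0158 with an estimated correlation). Against HMLE 33 of 35 fell (34 adjusted over the list alone; median −3.37; camera adjusted p = 9.04e-26, and adjusted p = 0.0125 with an estimated correlation). The block fit gave 34 and 33 lower genes, and NAMEC8 1 and 2 alone gave 34 lower genes in each comparison, with 1 higher against HMLE.

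Genes of the cyclic AMP pathway moved both up and down. The list of protein kinase A and cyclic AMP machinery had 4 of 42 tested genes higher and 9 lower in N8-CTx than in NAMEC8, also adjusted over the list alone, and 9 higher and 17 lower with NAMEC8 1 and 2 alone. Camera did not call it (adjusted p = 0.208), while fry called it down (adjusted p = 0.00217). The list of CREB target genes had 10 of 31 higher and 8 lower (13 and 10 adjusted over the list alone; camera adjusted p = 0.936, and fry adjusted p = 0.612). PDE4D, a cyclic AMP phosphodiesterase, fell from 37.8 ± 6.25 CPM in NAMEC8 to 9.36 CPM in N8-CTx (log2 change −2.01 ± 0.34 SE, edgeR adjusted p = 0.00195) after having been 13.6 ± 1.80 CPM in HMLE. The exchange factor RAPGEF3 and the adenylyl cyclase ADCY7 had log2 changes of 3.22 and 4.61, and the anchoring protein AKAP12 and CREB3L1 had −4.70 and −6.10. PRKACA, the catalytic subunit of protein kinase A (adjusted p = 0.67), the histone demethylase PHF2 (0.372) and CD44 (0.434) did not differ by the test. CREM (log2 change −1.41, adjusted p = 0.0539) and NR4A1 (1.57, 0.177), both induced by cyclic AMP in many cells, passed it only when NAMEC8 4 was left out (0.00115 and 0.000379) or, for CREM, with DESeq2 (0.0126). In the block fit CD44 was higher (log2 change 0.87, adjusted p = 0.0252, and 0.0481 with GC trends removed instead) and CREM was not called (0.246). That fit reads the change from N8-CTx and NAMEC8 4, single libraries, and NAMEC8 4 lay below the other NAMEC8 libraries for CD44 (723 CPM against 1100.0 to 1180.0 CPM).

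The largest rises from NAMEC8 to N8-CTx by fitted fold were those of CASP14, SPRR1B, VGLL1, the planar polarity gene VANGL2, LTB, the MIR205 host gene MIR205HG, ESPN, TMPRSS4, RAB25 and AP1M2. Among the largest falls by fitted fold were those of GNG11, LRRTM3, AGTR1, CDH6, ABCA8, POU3F3, SNTB1, MYADM, DOK5 and CYTIP, which had no count in N8-CTx and were at least 174-fold to 431-fold lower, bounds that do not rank them against measured falls. Of 18170 tested genes 4849 differed (edgeR quasi-likelihood F test, BH-adjusted), 2612 higher and 2237 lower. The block fit, in which this comparison rests on NAMEC8 4, called 4259, with 3503 in common and in the same direction. Without NAMEC8 4 the count was 9159, and with NAMEC8 1 and 2 alone it was 10112. Both fits lack NAMEC8 4, the other library without technical replicates. There the toxin cannot be told apart from a difference between libraries with and without them.

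To measure how far expression moved back without using a library on both sides, genes were taken from HMLE and NAMEC8 1 to 3, and the change was read as N8-CTx minus NAMEC8 4. Of 3400 genes called at least 2-fold apart, 88.9% lay toward HMLE in N8-CTx, 70.7% by at least 2-fold, and 3.41% lay at least 2-fold away from it. The share was 87.3% of 1593 genes higher in NAMEC8 and 90.4% of 1807 genes lower in NAMEC8. The slope of the change on the difference was 0.845, with r = 0.869 across genes, which are not independent replicates. On simulated unchanged libraries the same measure gave 50.6%. With NAMEC8 2 and 3, 1 and 3, or 1 and 2 in place of NAMEC8 4, each against genes from the other NAMEC8 libraries, the share was 75.2%, 81.6% and 78.1%.

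In the fit of all libraries 2184 of the 3895 genes that differed between NAMEC8 and HMLE (56.1%) moved back in N8-CTx, 939 of 1845 that had been higher and 1245 of 2050 that had been lower, and 83 moved further. Independent lists of these lengths would share 522 and 518 genes. These comparisons share the NAMEC8 libraries, and 20 simulations of unchanged N8-CTx libraries gave at most 1 gene moving back. The covariance of the fold changes was −3.45, against −0.20 in the simulation, a difference of −3.25. The simulated libraries carried no difference shared by the libraries without technical replicates. In the data the block term, estimated from NAMEC8 4 against NAMEC8 1 to 3, was called for 4398 of 18170 genes. These calls do not show whether N8-CTx shares that difference. As no shared difference was simulated, the simulation cannot tell how many genes such a difference would move back, or how it would change the covariance. Both fits called 1919 of the genes as moved back. Of the 2184, 1210 came within 2-fold of HMLE, and 342 went past HMLE and differed from it on the other side. Of the 3895, 600 still differed from HMLE in N8-CTx in the direction of NAMEC8. These counts rest on N8-CTx against HMLE, where no HMLE library lacks technical replicates. There a change of N8-CTx cannot be told apart from a difference between libraries with and without them. CDH1, EPCAM, ESRP1 and GRHL2 did not differ from HMLE by the test (adjusted p = 0.94, 0.566, 0.941 and 0.791).

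**Figure D3:**
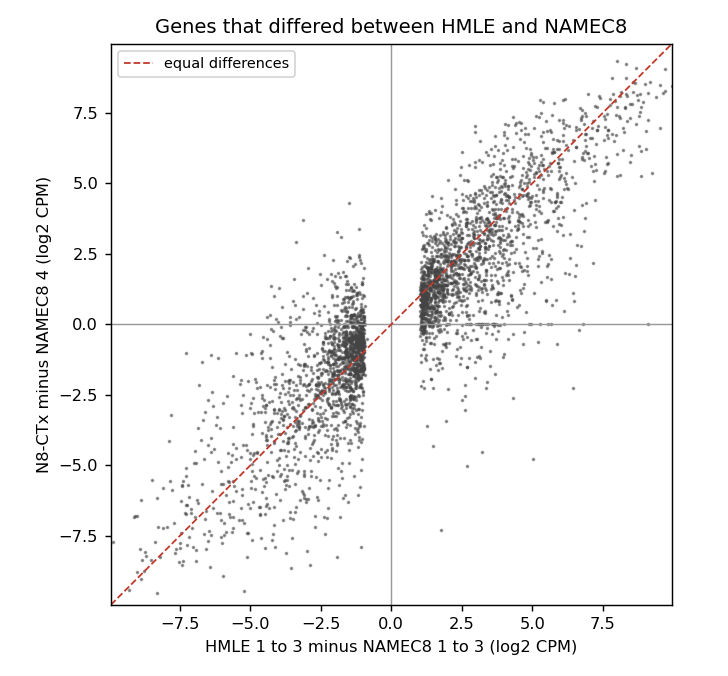
Log2 CPM difference of N8-CTx minus NAMEC8 4 (vertical axis) against HMLE 1 to 3 minus NAMEC8 1 to 3 (horizontal axis) for the 3400 genes at least 2-fold apart between the latter groups. Points are genes, the dashed line marks equal differences, and 88.9% of the genes have the same sign on both axes.

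Between N8-CTx and HMLE few junction genes and some basal genes differed by the test, which had 1 N8-CTx library. No HMLE library lacked technical replicates, so changes here cannot be told apart from a difference between libraries with and without them. Deviations of protein-coding genes from the mean of all libraries followed GC content at Spearman's rho 0.435 in N8-CTx and −0.27 to −0.0105 in HMLE. Of 34 junction genes 3 were higher and 1 lower in N8-CTx (3 and 0 adjusted over the list alone; camera adjusted p = 0.145), while NAMEC8 1 and 2 alone in the fit gave 19 and 4, and of 27 basal genes 6 were lower and none higher (7 adjusted over the list alone, and 14 lower and 4 higher with NAMEC8 1 and 2 alone; camera adjusted p = 0.07, and adjusted p = 0.00404 in the block fit). KRT15 was at 53.8 CPM against 255 ± 40.6 CPM in HMLE, and BNC1, a basal keratinocyte transcription factor, at 92.5 against 267 ± 23.7 CPM. In the list of mesenchymal cytoskeleton and adhesion 3 of 28 genes were higher and 7 lower (4 and 8 adjusted over the list alone, and 6 and 11 with NAMEC8 1 and 2 alone; camera adjusted p = 0.161, and adjusted p = 0.0349 in the block fit and 0.0225 with fry). The mesenchymal cadherins CDH2 and CDH11 lay below HMLE, with CDH2 13.2-fold lower and CDH11 at 0.460 CPM against 17.8 ± 2.49 CPM. VIM had a log2 change of −1.29 ± 0.30 SE (edgeR adjusted p = 0.0193), a call lost without HMLE 1 (0.0742) or HMLE 3 (0.0576), and SNAI2 one of −1.13 ± 0.27 SE (0.0199), a call lost without any HMLE library (0.0517 to 0.0649), in the block fit (0.0798) and with GC trends removed (log2 change −0.58, 0.0728).

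Matrix genes were divided between N8-CTx and HMLE, with 9 of 36 higher and 5 lower (12 and 12 adjusted over the list alone, 6 and 11 in the block fit, and 15 and 14 with NAMEC8 1 and 2 alone; camera adjusted p = 0.708). NID1 (2.36 CPM against 0.476 ± 0.0416 CPM) and the proteoglycan BGN (11.8 against 0.844 ± 0.247 CPM) were higher and tenascin C (TNC, 7.23 against 120 ± 26.2 CPM) and COL12A1 (26.3 against 215 ± 35.9 CPM) were lower. Among matrix proteases and their inhibitors TIMP2 was 15.3-fold higher and MMP1 was lower (0.167 against 22.9 ± 3.62 CPM), with 3 of 19 genes higher and 6 lower (4 and 9 adjusted over the list alone, and 4 and 10 with NAMEC8 1 and 2 alone; camera adjusted p = 0.065, and adjusted p = 0.0198 in the block fit and 0.0037 with fry). Glycolysis and hypoxia genes were lower for 9 of 28, also adjusted over the list alone, and for 14 with 2 higher with NAMEC8 1 and 2 alone (camera adjusted p = 0.00192, lost at adjusted p = 0.693 with an estimated correlation), among them LDHA, the lactate dehydrogenase A gene, at 1080.0 CPM against 3803 ± 135 CPM, and the carbonic anhydrase CA9. Mitochondrial transcripts were higher for 4 of 13 (11 adjusted over the list alone, 12 with NAMEC8 1 and 2 alone and none in the block fit; camera adjusted p = 0.00263, lost at adjusted p = 0.693 with an estimated correlation, at 0.336 in the block fit and at 0.0944 with fry).

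The largest rises above HMLE by fitted fold were those of RPL36AP37, LNCTAM34A, LAPTM5, the stress cytokine GDF15, SLC52A1, SMIM10L2A, TNXB, the phosphodiesterase PDE4C, ESPN and GREB1, and among the largest falls by fitted fold were those of YWHAZP3, FUCA2, TMEM200A, PAQR5, ITGA4, TFPI2, SV2A, TENM2 and MMP1. RPL36AP37 and YWHAZP3 are pseudogenes that can share reads with near-identical copies, so their values are uncertain, and neither call held in the block fit (adjusted p = 0.539 and 0.426) or without any HMLE library (0.133 to 0.136 and 0.0938 to 0.0964). Both were lost with GC trends removed (0.0522 and 0.0565), and that of YWHAZP3 also without NAMEC8 1 (0.0682) or NAMEC8 2 (0.0613) and with upper-quartile factors (0.051). The calls of ESPN and TMEM200A were lost in the block fit too (0.218 and 0.0694). Of 18170 tested genes 2832 differed between N8-CTx and HMLE (edgeR quasi-likelihood F test, BH-adjusted), 1430 higher and 1402 lower. The block fit called 1504 (567 higher and 937 lower), of which 1110 were in common and in the same direction. The count was 1115, 1107 and 1259 without HMLE 1, 2 or 3 in turn, 7050 without NAMEC8 4, and 8733 with NAMEC8 1 and 2 alone.

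**Figure D4:**
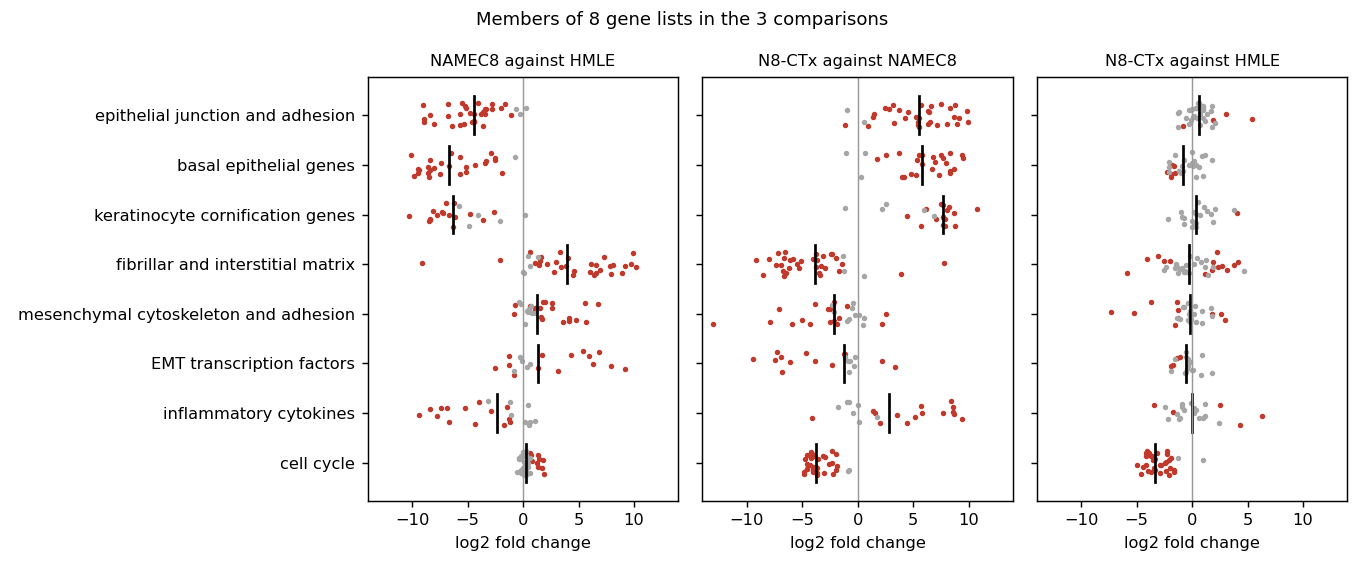
Log2 fold changes of the tested members of 8 gene lists fixed before the data were examined, in the 3 comparisons. Points are genes, red where the adjusted p was under 0.05 and grey otherwise, and black bars mark list medians, such as −4.42 and 5.55 for the junction list and −3.76 for the cell cycle list in N8-CTx against NAMEC8.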

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

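The pseudogene test, the tests of scaling and of 1 deviating library for the chromosome 20 run, and both cell cycle tests were chosen after the results were seen, and the other tests before their values were computed.

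Dixon's test was run on 112 measures, which were genes named in the texts and library measures such as depth. Among NAMEC8 libraries, 1 library lay far from the other 3 in 16 of these, all of them genes. Chance flags about 1 in 20 groups (5.6 of 112). In 15 of the 16 it was NAMEC8 4. Its values were above the others for BGN (193 CPM against 68.0 to 86.8), COL6A2 (1030.0 against 212 to 257), FBLN5 (567 against 384 to 388), GDF15 (25.2 against 1.56 to 5.01), MIR205HG (2.27 against 0.0488 to 0.293), NR4A1 (4.74 against 0.746 to 1.2), PAQR5 (24.7 against 14.2 to 15.5), RAPGEF3 (1.65 against 0.488 to 0.613) and RPL36AP37 (11.9 against 0 to 0.0799). They were below the others for CD44 (723 CPM against 1100.0 to 1180.0) and TFPI2 (27.7 against 52.5 to 56.6). For LTB, SPRR1B and VGLL1 (0.0223 CPM each) and SBSN (0.0668 CPM) the other 3 libraries had no count, and these values rest on few reads. NAMEC8 2 lay apart for IL1RN (0.0307 CPM against 0). With the other 3 libraries at 0, Dixon's test flags any count. The flags of LTB, SPRR1B, VGLL1, SBSN and IL1RN therefore add nothing to the comparison with chance.

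The difference of NAMEC8 4 from NAMEC8 1 to 3 followed the GC content of genes (Spearman's rho 0.569 across 13945 protein-coding genes) and gene length (rho −0.304), so library preparation may account for a part. It was not the whole, since 17.2 to 25.4% of genes still lay at least 2-fold apart with the GC trend removed, against 5.92 to 13.6% among NAMEC8 1 to 3. Processed pseudogenes were at least 4-fold apart 5.91 times as often as protein-coding genes (31.3% of 643 against 5.29%). Reads divided differently between near-identical copies would give this. The gene types were not matched for expression level, and low counts can give it too, so the ratio cannot tell these apart. A difference in culture was not tested, as the labels give no groups within NAMEC8. The real grouping of HMLE and NAMEC8 gave the most calls of 35 splits (rank 1, 3895 genes, with 377 in the next). Any other split puts the large differences between these cells inside a group. The rank was therefore set in advance and tests neither batch nor culture.

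The fall of cell cycle genes in N8-CTx could come from a batch shared with NAMEC8 4, but NAMEC8 4 differed from NAMEC8 1 to 3 by a median log2 of only −0.104 for these 35 genes. Against NAMEC8 4 alone the median was −3.66, with 35 of 35 genes lower, and −3.56 with the GC trend removed, so GC content does not account for it. Whether the toxin or the growth state of this 1 culture lowered these genes was not tested.

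The run on chromosome 20 was not a matter of GC content (lowest run median 0.997 above other genes with the trend removed) or of 1 deviating library (lowest run median 1.04). The median of −0.00432 outside the run follows from the scaling itself, and the 93.7% of run genes above the median of other genes follow from how the run was chosen, so neither tests scaling or extra copies of the segment. The run less the other genes of the same library, a difference in which a scaling factor cancels, was 1.21, 1.12, 1.04 and 1.17 in NAMEC8 1 to 4, against −0.0416 to 0.0798 among HMLE libraries, so scaling was not the cause. In N8-CTx the run, less other genes, was 1.73-fold above HMLE (1.43-fold with GC trends removed). For N8-CTx minus NAMEC8 4, a difference of 2 single libraries, the run median less that of other genes was −0.472. No DNA was measured, and the explanation stays open.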

How the results depend on the processing

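No gene called in the main fit was called in the opposite direction under another setting, but the balance of higher and lower calls turned. For N8-CTx against NAMEC8 it went from 2612 higher and 2237 lower to 2017 and 2242 in the block fit, 2236 and 2441 there with GC trends removed and 2849 and 3091 with DESeq2. For NAMEC8 against HMLE it went from 1845 and 2050 to 1861 and 1745 with the filter of 1 CPM in 3 libraries, 1992 and 1904 without N8-CTx and 2939 and 2820 with replicates 1 to 3 without a block. For N8-CTx against HMLE, 1430 and 1402 in the main fit, lower calls also prevailed without a filter (1313 and 1470), for protein-coding genes (1419 and 1471), against a 2-fold change (412 and 433) and without HMLE 1, 2 or 3 (495 and 620, 482 and 625, 560 and 699); the cause was not tested. Counts within 1.5 times of the main ones were found with other scaling factors, robust=FALSE, other filters, the first technical library only, limma-voom, protein-coding genes only and GC trends removed. Against a 2-fold change the counts were 1935, 2509 and 845 for NAMEC8 against HMLE, N8-CTx against NAMEC8 and N8-CTx against HMLE, instead of 3895, 4849 and 2832, since that test asks for a larger change. With 1 library left out they ranged over 2573 to 5805, 3752 to 9159 and 1107 to 7050. The highest counts were those without NAMEC8 4. With NAMEC8 1 and 2 alone, a choice added after the data were seen, they were 6029, 10112 and 8733. In fits without NAMEC8 4, N8-CTx is the only library without technical replicates. Its changes there, also those of genes and lists, cannot be told apart from such a library difference. The same holds for N8-CTx against HMLE in the main fit, as no HMLE library lacks technical replicates. For N8-CTx against HMLE, DESeq2 gave 4590 (44.1% higher), the block fit 1504 (37.7% higher) and the block fit with GC trends removed, also added after, 1823 (39.4% higher), against 50.5% in the main fit; the cause was not tested.

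The share of genes toward HMLE (88.94%) was 87.79% with shared controls, 75.23, 81.64 and 78.13% in the 3 splits where NAMEC8 4 helped to define genes, 92.56% for genes of at least 4-fold, 83.56% for genes of any fold, and 88.19 to 90.52% with 1 library left out; the cause was not tested.

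Same-numbered HMLE and NAMEC8 libraries did not deviate together (r = −0.145, 0.0978 and 0.0166), and differently numbered ones gave −0.167 to 0.127. These values gave no sign that the numbers pair samples, but cannot exclude a pairing with a small shared effect. The replicate block gave 5314 genes for NAMEC8 against HMLE, and the same 6 libraries gave 5759 without it. With the block the luminal list was not called (0.0689) and the histone list was (0.0268), but as NAMEC8 4 and N8-CTx were also left out, this cannot be put down to the block.

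Among named genes and lists past the threshold in either setting, the direction turned for SBSN and for 1 list, and changes of sign without a call in either were not counted. SBSN in N8-CTx against HMLE had a log2 change of −0.3251 in the block fit (adjusted p = 0.698; 0.0854 to 0.0942 without any HMLE library), and the endothelial list in NAMEC8 against HMLE went down with fry (adjusted p = 0.0325); the cause was not tested. Of other values of named genes 3915 stayed, 225 lost their call and 10 gained one, and of those of lists 230 stayed, 22 lost and 28 gained one. Depth limits genes of few counts, where folds are bounds.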

Other observations

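Other lists moved in part or not at all in NAMEC8 against HMLE. Luminal mammary genes were lower for 10 of 17 and higher for 4 (10 and 6 adjusted over the list alone; camera adjusted p = 0.031, lost at adjusted p = 0.265 with an estimated correlation and at 0.0711 in the block fit). EGF receptor ligands and receptors were lower for 9 of 22 and higher for 3 (10 and 3; 0.00522, lost at adjusted p = 0.0788 with an estimated correlation). Camera gave no list call for matrix proteases (9 of 19 higher, 5 lower; 0.136), TGF-beta and BMP (7 of 30 higher, 7 lower; 0.87), Wnt (10 of 32 higher, 9 lower; 0.728), CREB targets (8 of 31 higher, 6 lower; 0.827) and PKA and cAMP machinery (12 of 42 higher, 9 lower; 0.365). The same held for stem markers (5 of 18 higher, 7 lower; 0.858), receptor tyrosine kinases (11 of 22 higher, 5 lower; 0.0724), interferon response (2 of 32 higher, 7 lower; 0.827), glycolysis (2 of 28 higher, 7 lower; 0.136), sterol synthesis (2 of 24 higher; 0.707) and unfolded protein stress (3 of 22 lower; 0.365). Endothelial (2 of 6 higher, 1 lower; 0.69), leukocyte (1 of 7 higher, 3 lower; 0.136), adipocyte (2 of 8 higher; 0.136) and histone lists (3 of 13 lower; 0.104) were not called by camera. Fry called 9 of these lists: proteases (adjusted p = 0.00183), PKA and cAMP machinery (0.00131), tyrosine kinases (0.0014) and adipocyte (0.0178) up, and Wnt (0.0213), glycolysis (0.0157), leukocyte (0.00644), endothelial (0.0325) and histones (0.0157) down.

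In N8-CTx against NAMEC8 the smooth muscle list was lower for 5 of 12 and higher for 1 (camera adjusted p = 0.0165, lost at adjusted p = 0.314 with an estimated correlation). Lists without a camera call were luminal (7 of 17 higher, 1 lower; 0.0635), proteases (3 of 19 higher, 7 lower; 0.125), TGF-beta and BMP (6 of 30 higher, 9 lower; 0.302), Wnt (8 of 32 higher, 8 lower; 0.936), stem markers (2 of 18 higher, 4 lower; 0.437), EGF receptor (6 of 22 higher, 2 lower; 0.458), tyrosine kinases (7 of 22 higher, 7 lower; 0.192), interferon (11 of 32 higher, 3 lower, and 6 and 3 in the block fit; 0.0635) and glycolysis (4 of 28 higher, 8 lower; 0.0529, and 0.0119 in the block fit). The remaining lists were sterol synthesis (3 of 24 higher, 3 lower; 0.669), unfolded protein stress (4 of 22 higher, 4 lower; 0.669), endothelial (0 of 6; 0.635), leukocyte (2 of 7 higher; 0.241), adipocyte (1 of 8 lower; 0.87), mitochondrial (0 of 13; 0.371) and histones (4 of 13 higher; 0.226). Fry called 8 of these lists: luminal (adjusted p = 0.000308), EGF receptor (0.0045), interferon (0.0175), leukocyte (0.0374) and histones (0.01) up, and proteases (9.8e-05), TGF-beta and BMP (0.025) and tyrosine kinases (0.00528) down. With NAMEC8 1 and 2 alone 7 of 13 mitochondrial transcripts were higher.

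In N8-CTx against HMLE unfolded protein stress genes were higher for 2 of 22 and lower for 4 (2 and 7 adjusted over the list alone, and 4 and 10 with NAMEC8 1 and 2 alone; camera adjusted p = 0.145, and 0.000185 in the block fit). Interferon genes were higher for 6 of 32 and lower for 3 (8 and 3; 0.0613, and 0.0225 with fry), for 2 and 0 in the block fit, and for 19 and 5 with NAMEC8 1 and 2 alone in the fit. Fry also called the transition's transcription factors (0.0263) and EGF receptor genes (0.0152) down, which camera did not (0.07 and 0.157).

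NAMEC8 3 held 493 genes with 1 to 3 counts, against 2801 to 4508 in the other libraries. Of 4158 genes under 0.5 CPM in NAMEC8 1 and 2, 62.3% had no count in NAMEC8 3, against 17.2% in NAMEC8 4. Of 9821 genes of at least 5 CPM in NAMEC8 1 and 2, 0 had no count in NAMEC8 3.

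Other runs of neighbouring genes were 44 genes on chromosome 16 from CMIP to DEF8 (median −0.551 in NAMEC8 minus HMLE) and, in N8-CTx minus NAMEC8 4, 48 genes on chromosome 13 from SLC25A15 to VPS36 (0.689), 60 genes on chromosome 16 from ZNRF1 to DEF8 (1.03) and 50 genes on chromosome 20 from RBL1 to NCOA3 (−0.729). The longest run in 100 shuffles was 0 genes for the first difference and 22 genes for the second. The medians given here are not taken less those of other genes, which lay at −0.154 to −0.146 in the second difference.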
